A study of Mus musculus with 14 samples.

How the data were processed

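RNA from 14 mouse lungs was measured on 14 one-colour (Cy3) Agilent arrays of 62976 spots, 3671 of them controls. Per the labels RNA was isolated with phenol and chloroform, cleaned on a column and labelled with the Quick Amp chemistry. Per the file headers the scans were read with Feature Extraction 10.7.3.1, and the deposited array files hold intensity values of that program's processed signal, background-subtracted and spatially detrended but not scaled between arrays. The median signal of each spot and of its local background are deposited as intensity too. The mean signal, planned for an alternative background correction, is not in the files used here, so that the median signal took its place. The authors' deposited values, in a table for the series, hold log2 values of 32177 probes: each column equals log2 of the processed signal of its array minus 1 constant, with blanks for probes not well above background. Its column medians were −0.05, −0.03, −0.29, −0.50 and −0.49 for control 1 to 5, 0.30, −0.30 and −0.37 for VCF, −0.36, 0.16 and −0.34 for CCF and −0.17, −0.52 and −0.49 for RCF. The scale and direction of that table are thus known from the values and it is not centred per gene, while the origin of the array constants is not given in the sources used here.

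For each array log2 of the processed signal was taken, minus the array's 75th percentile over spots other than controls. Spots that Feature Extraction marked as outliers were left out, and spots of 1 probe were averaged (300 of 56605 probes are spotted more than once). Probes well above background on at least 3 of the 14 arrays were kept (37983). Gene symbols came from the RefSeq accession that the array files give for a probe: 32994 probes had 1 symbol and 23611 none. Of several probes of a gene the one with the highest mean was used (5922 genes), and a probe without a symbol stood alone, which left 30579 genes, 17290 with a symbol. The array was designed on an older mouse assembly than the annotation, so that no positions are given. Log2 values for single arrays are on this scale, where 0 is the 75th percentile.

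The 75th percentile of the processed signal was divided by the median signal of negative control spots, which was not background-subtracted. This ratio was 16.3, 14.6, 21.5, 36.6 and 29.0 in control 1 to 5, 4.78, 20.1 and 22.7 in VCF, 26.1, 5.98 and 24.9 in CCF and 6.25, 59.6 and 43.2 in RCF. The share of probes above background ran from 49.4% in VCF 1 to 71.3% in RCF 2. The number of arrays limits the precision of each difference. Across genes, arrays of the same group correlated at a median r of 0.968 (19 pairs) and of different groups at 0.963 (72 pairs), on the same slide at 0.969 (30 pairs) and on different slides at 0.961 (61 pairs). Genes are not independent replicates in these values. Slides 1 and 2 were scanned on 1 day and slide 3 on another.

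Groups were taken from the labels. Limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table for reading, was fitted to all 14 arrays with the 4 groups sharing the spread and without covariates, and moderated two-sided tests were made for 7 comparisons: each fibre against control, the mean of the 3 fibres against control, and the fibres against each other. Adjusted p is Benjamini-Hochberg within a comparison, with a threshold of 0.05. Where a group lay below background, the fold was computed against the background level and given as "at least". A set of 33 gene lists (558 entries, 522 measured) for lung cell types, blood cells, stress and injury programmes and neighbouring tissues was tested with camera and a preset correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether the genes of a list differ from the other genes. With an estimated correlation camera takes the correlation among the genes of a list from these arrays. Fry, also run, asks whether the genes of a list move on balance one way and does not compare them with other genes. Members past the threshold were counted over all genes and adjusted over the list alone.

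Genes were named by a rule: in each comparison with control the 8 largest rises and the 8 largest falls past the threshold whose fibre arrays all lay on 1 side of the control mean (filled to 4 by p, as values only), 4 members of each list past the threshold (at most 8 lists), at most 2 members of other lists, and 20 genes known from particle exposure, of which 19 were tested. Between fibres the numbers were 4 and 2. Predicted, clone and accession-like symbols were passed over, and of the genes so chosen the text names those of clearest function. The comparisons, the rule, the lists and most alternatives were fixed before the data were examined. Pairing of arrays by replicate number was decided by a rule on residual correlations, before the blocked fits were compared. Arrays with the same number correlated above 0.1 in 12 of 18 pairs (median r 0.181), and others in 11 of 54 (median r −0.0352). Most of the 18 share a slide, as do all pairs of VCF and control but, of RCF and VCF, only that of number 1. On 1 slide, pairs of different numbers ran from −0.13 to 0.50, and across slides those of 1 number from −0.28 to 0.21. For VCF and control the rule can thus rest on slides alone. For VCF and control (0.17, 0.19 and 0.62) and for RCF and VCF (0.30, 0.20 and 0.21) each pair was above 0.1, and the value with replicate number as a block is given beside these comparisons. The labels call the samples independent.

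The pipeline was tested on simulated data: 100 genes at a log2 fold of 1 and 100 at 2 were set into simulated unchanged arrays of the CCF against control design. Each gene was drawn independently and without slide effects, so that the effect of correlated genes or of slides on calls was not tested. At the smaller fold 34% and at the larger 66% were recovered, with 8 false calls among 108. A neutrophil list shifted by −1 gave a camera adjusted p of 6.56e-11 and 0 of the 32 other lists passed.

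Alternatives were quantile scaling, normexp background (offset 50) with either scaling, the authors' table, no background filter or one on all 14 arrays, the mean of a gene's probes, slide as a fixed or random block (limma's estimated slide correlation was 0.331), single slides, replicate number as a block, fits of the compared groups alone, a trended robust prior, array weights, other thresholds, and leaving out each array in turn. Where an array left out leaves 2 in a group, the shared spread is used. Chosen after the data were seen were the fits without VCF 1, CCF 2 and RCF 1, of the first scan day only and with scan day as a block, the use of each gene's second-highest probe, normexp on the median signal, and the marker lists of squamous epithelium and liver (16 genes each). The sources used here give no histology or cell counts.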

Results

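Whole-lung RNA from male C57BL/6N mice was measured 1 month after fibre had been placed in the trachea at 200 µg per mouse, on 14 one-colour arrays with 1 array per mouse. The groups were 5 controls given the vehicle, and 3 mice each for a carbon fibre before recycling (VCF), the same material after carbonization (CCF) and after firing (RCF). Arrays stood on 3 slides. Slide 1 held control 1 and 2, VCF 1 and 2, CCF 1 and 2 and RCF 1, slide 2 held control 3, VCF 3 and CCF 3, and slide 3 held control 4 and 5 and RCF 2 and 3. The 75th percentile of intensity was 1060, 891, 1105, 1831 and 1448 in control 1 to 5. It was 277, 1173 and 1201 in VCF 1 to 3, 1616, 323 and 1294 in CCF 1 to 3, and 375, 2953 and 2118 in RCF 1 to 3, so that VCF 1, CCF 2 and RCF 1 were dim. Differences below are in log2 with limma's standard error (±), for n = 3 fibre and n = 5 control arrays (n = 3 against 3 between fibres), over 30579 genes (30574 where RCF takes part), and "adjusted p" is Benjamini-Hochberg over all of them. A gene set list has an adjusted p from camera with a preset correlation between genes, followed by the p that camera gives with the correlation estimated from these arrays. With the latter 0 of 33 lists passed the threshold in any of the 7 comparisons.

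In VCF lungs Stfa1, Cstdc4 and Spp1 rose against vehicle, and Crabp1, Ckap2 and Cdca3 fell. With replicate number as a block, which also drops control 4 and 5, no named gene passed limma (adjusted p = 0.316 to 0.375 for these). Stfa1 and Cstdc4, stefin-family protease inhibitors made by neutrophils, rose by 2.69 ± 0.37 (6.47-fold, adjusted p = 0.0401) and 2.50 ± 0.38 (5.66-fold, adjusted p = 0.0484). Spp1, the secreted phosphoprotein osteopontin of macrophages, rose by 1.57 ± 0.24 (2.97-fold, adjusted p = 0.0484). Crabp1, which binds retinoic acid, fell by 2.23 ± 0.23 (4.69-fold, adjusted p = 0.0192), and the mitotic genes Ckap2 and Cdca3 fell by 1.45 ± 0.23 (2.73-fold, adjusted p = 0.0484) and 1.30 ± 0.16 (2.46-fold, adjusted p = 0.0318).

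Among the other named genes past the threshold in VCF, Eppin, a protease inhibitor of the epididymis, rose by 2.17 ± 0.28, the transcription factor gene Tcf23 by 1.79 ± 0.28 and Doc2b, a calcium sensor of exocytosis, by 1.76 ± 0.28. Ces2e, a carboxylesterase, fell by 1.18 ± 0.13 (adjusted p = 0.02), Plvap, a component of endothelial diaphragms, by 1.14 ± 0.17 and Colq, the collagen tail of acetylcholinesterase, by 1.06 ± 0.17. Kif20a, a kinesin of cytokinesis, fell by 1.06 ± 0.14, and the proliferation marker Mki67 by 0.97 ± 0.15 (adjusted p = 0.0484). Shcbp1, a midbody gene, fell to a level that was not above background in VCF, at least 1.32-fold lower. For each of these genes all 3 VCF arrays lay on one side of the control mean. In all 26 genes passed limma's threshold, 9 higher and 17 lower, 20 of them with a gene symbol.

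Gene lists showed broader shifts in VCF. Of 25 cell cycle genes measured, 1 fell over all genes and 16 fell when adjusted over the list alone, with a list median of −0.60 (camera adjusted p = 1.14e-16, adjusted p = 0.0703 with an estimated correlation). Of 15 neutrophil markers 0 passed over all genes and 7 rose when adjusted over the list alone, at a median of 0.90 (adjusted p = 1.11e-06, adjusted p = 0.118 with an estimated correlation), with Stfa2 at 2.36 ± 0.43 and the collagenase gene Mmp8 at 1.65 ± 0.31. All 9 erythroid genes fell when adjusted over the list alone and 0 over all genes, at a median of −1.36 (adjusted p = 2.46e-09, adjusted p = 0.118 with an estimated correlation). The beta-globin gene Hbb-b2 stood at −1.58 ± 0.38, a value that probes for near-identical globin copies share. B cell and plasma cell markers had a median of −0.58 with 8 of 14 lower when adjusted over the list alone (adjusted p = 2.76e-10, adjusted p = 0.0604 with an estimated correlation). For T cell and NK cell markers it was −0.56 with 11 of 18 (adjusted p = 4e-10, adjusted p = 0.0604 with an estimated correlation). Thymus genes, with 4 of 8 measured, did not pass at −0.44 (camera adjusted p = 0.152), but lay at −0.41, −0.55 and −0.43 in VCF 1 to 3, where the cell cycle list lay at −0.75, −0.77 and −0.36, the T and NK list at −0.63, −0.53 and −0.42 and control arrays from −0.36 to 0.45 for thymus. In the neutrophil, erythroid, B cell and T and NK lists 0 members passed over all genes by limma, where 7, 9, 9 and 11 had an unadjusted p under 0.05. The B cell receptor chain Cd79b was at −0.95 ± 0.19 (adjusted p = 0.0909) and the T cell adhesion gene Cd2 at −0.67 ± 0.11 (adjusted p = 0.0573).

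Smaller shifts passed camera in 9 further lists in VCF, with 0 members past limma's threshold over all genes. Ciliated cell genes had a median of 0.25, with 5 of 20 higher when adjusted over the list alone and 7 higher and 1 lower at an unadjusted p under 0.05 (adjusted p = 3.53e-05, adjusted p = 0.318 with an estimated correlation). MHC class II genes had a median of −0.32, with 1 higher and 6 lower of 14 over the list alone and at an unadjusted p under 0.05 (adjusted p = 9.12e-05, adjusted p = 0.168 with an estimated correlation). Extracellular matrix genes stood at −0.20, with 1 higher and 4 lower of 28 over the list alone and 1 and 7 at an unadjusted p under 0.05 (adjusted p = 0.000185, adjusted p = 0.0957 with an estimated correlation). The collagen gene Col1a1 was at −0.75 (adjusted p = 0.336). Without VCF 3 the MHC class II list stood at −0.49 and without VCF 1 the matrix list at −0.32. The xenobiotic metabolism list stood at 0.34, with 2 higher and 1 lower of 14 over the list alone and at an unadjusted p under 0.05 (adjusted p = 0.002, adjusted p = 0.118 with an estimated correlation). Its lower member was Cyp1a1, the classic target of the aryl hydrocarbon receptor, at −1.90 ± 0.53. Heat shock genes stood at 0.27 with 0 of 12 over the list alone and 3 higher at an unadjusted p under 0.05 (adjusted p = 0.000172, adjusted p = 0.351 with an estimated correlation), and the chaperone gene Hspa1a at 2.06 ± 0.60 (adjusted p = 0.243). The heat shock list stood at 0.18 without control 4 and 0.43 without VCF 2.

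The weakest VCF lists lost the call without some single arrays, some at smaller and some at larger medians. The eosinophil, basophil and mast cell list stood at −0.27 with 0 of 12 members over the list alone and 3 lower at an unadjusted p under 0.05 by limma (adjusted p = 0.0083, adjusted p = 0.118 with an estimated correlation). It was lost without control 2 (−0.21, adjusted p = 0.0970) and without VCF 1 (−0.32, adjusted p = 0.0582), and stood at −0.41 without control 4, −0.54 without VCF 2 and −0.55 with slide as a fixed block. Alveolar type 2 cell genes stood at −0.09, or 0.00 with normexp background and quantile scaling, with 2 of 20 lower over the list alone (adjusted p = 0.0253, adjusted p = 0.318 with an estimated correlation). That call was lost without VCF 2 (−0.076, adjusted p = 0.110) and VCF 3 (−0.069, adjusted p = 0.120), and the list stood at −0.24 without VCF 1, −0.13 without control 2 and −0.054 without control 4. Alveolar type 1 cell genes stood at −0.19, with 0 of 13 over the list alone and 3 lower at an unadjusted p under 0.05 by limma (adjusted p = 0.0253, adjusted p = 0.351 with an estimated correlation). Without control 2, control 3 or VCF 2 the list stood at −0.14, −0.23 or −0.096 (adjusted p = 0.0585, 0.0649 or 0.323), and without VCF 1 and VCF 3 at −0.31 and −0.12. Cholesterol synthesis genes stood at −0.23, with 0 of 18 over the list alone and 3 lower at an unadjusted p under 0.05 by limma (adjusted p = 0.0262, adjusted p = 0.318 with an estimated correlation). They stood at −0.17 (adjusted p = 0.0970) without control 2 and −0.09 (adjusted p = 0.409) without VCF 1.

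The VCF calls depended on the arrays and blocks used. With slide as a fixed block 12 of the 26 genes remained among 35, and Stfa1 (2.52, adjusted p = 0.0641), Spp1 (1.56, adjusted p = 0.0846), Cstdc4, Tcf23, Doc2b, Shcbp1 and Colq no longer passed, while all 26 remained among 95 with slide as a random block. All 26 had the same sign within slide 1 and within slide 2, at 2.30 and 3.05 for Stfa1, 2.02 and 0.67 for Spp1, −2.30 and −1.89 for Crabp1 and −1.20 and −0.80 for Mki67. The genes were called on these same arrays, so that such agreement in sign, here and below, is largely given by the choice. Within slides 1 and 2 the neutrophil median was 0.94 and 1.08, that of cell cycle −0.86 and −0.59, of erythroid genes −1.15 and −1.93, of B cells −0.55 and −0.84, and of T and NK cells −0.64 and −0.45. With slide as a fixed block these medians were 0.67, −0.74, −1.35, −0.66 and −0.56. With replicate number as a block 0 genes passed limma (2308 at an unadjusted p under 0.05), and 18 lists passed camera, all 14 of these among them. Leaving out control 1 to 5 in turn gave 2, 6, 22, 0 and 8 genes, and leaving out VCF 1 to 3 gave 0, 2 and 28. The counts of 0, without control 4 and without VCF 1, came with 2284 and 3403 genes at an unadjusted p under 0.05 by limma. For such counts, here and below, chance alone would give a share of about 0.05 of the 30579 genes. Of the 15 named genes past the threshold, 14, 11, 9, 15 and 10 were lost without control 1 to 5, and 15, 15 and 5 without VCF 1 to 3.

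**Figure D1:**
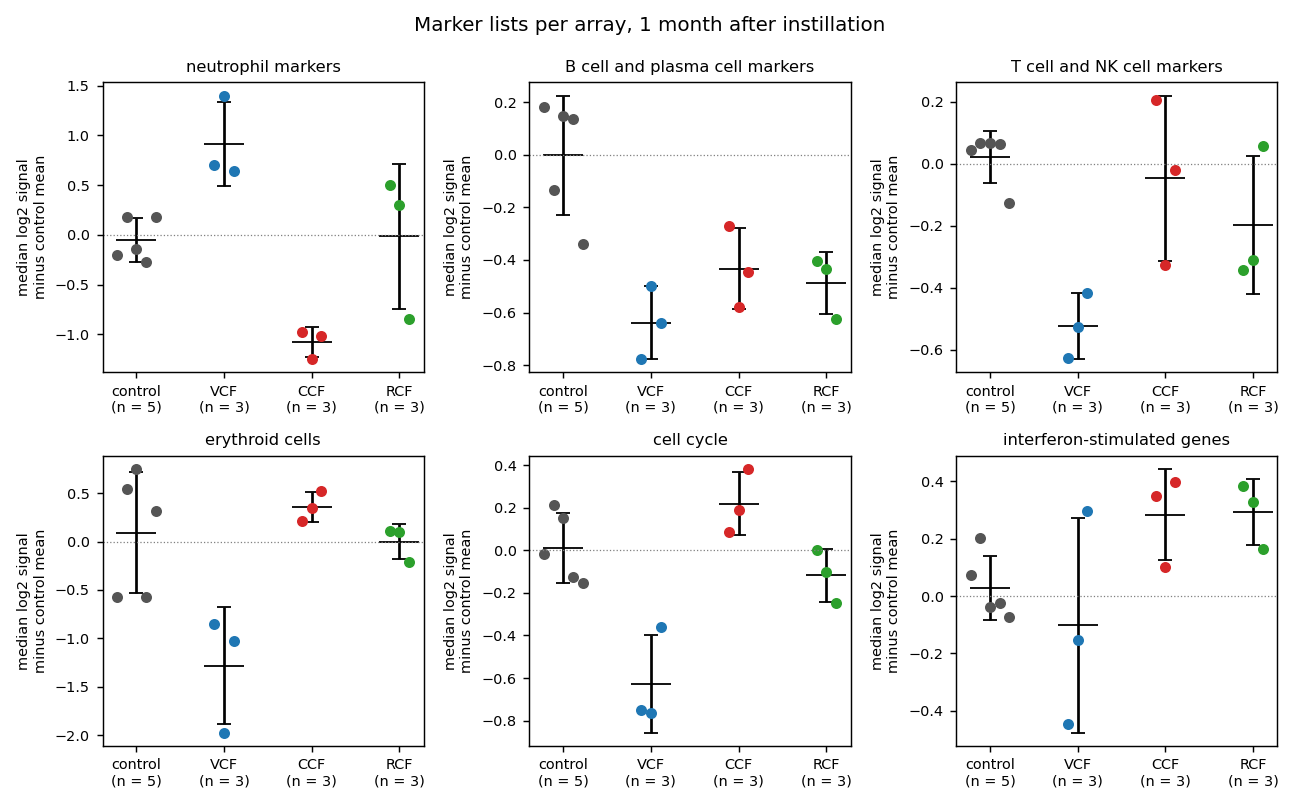
Per-array median of 6 gene lists in log2, minus the control mean, for control, VCF, CCF and RCF; points are arrays and bars the group mean ± SD. Neutrophil medians lie at 0.70, 1.40 and 0.64 in VCF 1 to 3 and at −0.97, −1.25 and −1.01 in CCF 1 to 3.

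In CCF lungs 6 of 15 neutrophil markers fell against vehicle, as did the B cell gene Cd79b, and Stat2, Nr1d2 and Per2 rose. S100a8 and S100a9, the calcium-binding subunits of calprotectin, fell by 1.85 ± 0.36 (3.60-fold, adjusted p = 0.0174) and 1.68 ± 0.29 (3.20-fold, adjusted p = 0.0134). Cxcr2, the receptor that guides neutrophils to chemokines, fell by 2.26 ± 0.52 (4.80-fold, adjusted p = 0.031), and Retnlg, a resistin-like gene of granulocytes, by 1.69 ± 0.31 (3.24-fold, adjusted p = 0.0144). Cd79b fell by 0.98 ± 0.19 (1.97-fold, adjusted p = 0.0174), and Stat2, which carries type I interferon signals, rose by 0.85 ± 0.13 (1.80-fold, adjusted p = 0.00806), with its other probe on the opposite side. For each of these genes, and for those named below as past the threshold, all 3 CCF arrays lay on one side of the control mean.

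The neutrophil list had a median of −1.11, with 6 of its 15 measured members lower over all genes and 7 lower adjusted over the list alone (camera adjusted p = 0.00158, adjusted p = 0.765 with an estimated correlation). The list medians of CCF 1 to 3 were −0.97, −1.25 and −1.01 against the control mean. B cell and plasma cell markers stood at −0.36, with 1 of 14 lower over all genes and 5 over the list alone (adjusted p = 0.0199, adjusted p = 0.765 with an estimated correlation). Without CCF 2, 1 of the dim arrays, the B cell list stood at −0.28 (adjusted p = 0.0611). Interferon-stimulated genes stood at 0.31, with 1 of 23 higher over all genes and over the list alone (adjusted p = 0.0199, adjusted p = 0.929 with an estimated correlation) and 0.27 without CCF 3 (adjusted p = 0.254). Ifit2, an interferon-induced gene, was at 0.71 (adjusted p = 0.0705). The remaining 30 lists did not pass camera.

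The largest named rises in CCF were in genes of varied function. Gmnc, a regulator of multiciliated cells, rose by 1.98 ± 0.23 (3.94-fold, adjusted p = 0.00451), Eppin by 2.10 ± 0.28 (4.30-fold, adjusted p = 0.00608) and the zinc finger gene Zfp560 by 2.09 ± 0.28 (4.24-fold, adjusted p = 0.00608). Scai, a transcriptional corepressor, rose by 1.84 ± 0.23 and the zinc importer gene Slc39a10 by 1.80 ± 0.26. Zfp963 rose by 1.83 ± 0.42 and the glycosyltransferase gene Galnt5 by 1.86 ± 0.41, with its other probe on the opposite side. Gna12, a G protein subunit, rose at least 2.36-fold from a level not above background in control (adjusted p = 0.031). The clock genes Nr1d2 and Per2 rose by 0.95 ± 0.15 (adjusted p = 0.00987) and 1.24 ± 0.25 (adjusted p = 0.0208), the latter with its other probe opposite, while the clock list did not pass at 0.21 (camera adjusted p = 0.0812). Lox, which crosslinks collagen, rose by 1.04 ± 0.24 (adjusted p = 0.0298), and the eosinophil chemokine receptor gene Ccr3 fell by 1.30 ± 0.25 (adjusted p = 0.0173). Nfkbia and Gadd45b, both induced by NF-kB, fell by 0.87 ± 0.18 (adjusted p = 0.0222) and 0.90 ± 0.16 (adjusted p = 0.0134).

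The deepest falls in CCF were in 8 genes that moved together from array to array. Rhox3a, a reproductive homeobox gene, fell by 4.60 ± 0.92 (24.3-fold, adjusted p = 0.0192) and Dmrtb1, a testis transcription factor gene, by 4.48 ± 0.96. Vpreb2, the surrogate light chain of pre-B cells, fell by 3.84 ± 0.99, the receptor gene Mrgprg by 3.77 ± 0.69 and the growth factor gene Fgf2 by 3.62 ± 0.82. Itga1, an integrin subunit, fell by 3.47 ± 0.67, Lypd6b by 3.39 ± 0.64 and the NK cell receptor gene Klra1 by 3.35 ± 0.57. The other probes of Dmrtb1 and Lypd6b lay on the opposite side of 0. The mean of the 8 genes was 1.80, 1.89, 0.42, 2.49 and 3.09 in control 1 to 5 and −1.92, −0.75 and −2.96 in CCF 1 to 3, but also 0.35 and −0.68 in VCF 2 and 3 and 0.03 in RCF 1. With each group's mean removed, 381 probes, 155 of them named, moved with the mean of these genes at r of 0.9 or more. They took in 74 of the 675 called falls in CCF and 68 of the 143 called falls that were more than 4-fold.

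In CCF, 1832 genes passed limma's threshold, 1157 higher and 675 lower, of which 1067 had a symbol, 775 higher and 292 lower. Among 481 of these genes with a second probe past the background filter, 294 (61.1%) had both probes on the same side. Without control 1 to 5 in turn the count was 893, 2717, 1977, 533 and 877, and without CCF 1 to 3 it was 531, 258 and 629. Without those arrays 15, 2, 2, 17 and 15, and 24, 24 and 24, of the 38 named genes past the threshold were lost. The 9 that passed without each array in turn were Eppin, Zfp560, Gmnc, Scai, Slc39a10, Klra1, Stat2, Nr1d2 and Polk. With slide as a fixed block 1390 of the 1832 remained among 1869, and 1832 among 2945 with slide as a random block. Of the 1832, 1832 and 1831 had the same sign within slide 1 and slide 2, at −3.63 and −4.29 for Rhox3a, −1.68 and −1.40 for S100a9 and −1.11 and −0.85 for Cd79b. The neutrophil median was −1.36 with slide as a fixed block, −1.68 within slide 1 and −1.04 within slide 2. That of B cells was −0.48, −0.43 and −0.44, and that of interferon-stimulated genes 0.27, 0.09 and 0.44.

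The fired fibre was compared with vehicle as the end product of recycling. In RCF lungs a few genes of varied function rose. Zfp518a, a zinc finger gene, rose by 1.43 ± 0.20 (2.70-fold, adjusted p = 0.0307), and Fndc3a by 1.30 ± 0.14 (2.47-fold, adjusted p = 0.00913), with 1 other probe opposite. Fpgt, an enzyme of fucose salvage, rose by 1.07 ± 0.11 (2.09-fold, adjusted p = 0.00913), and Zbtb34, a zinc finger gene, by 1.25 ± 0.18 (2.38-fold, adjusted p = 0.0312). Itpkb, an inositol trisphosphate kinase, fell by 1.19 ± 0.19 (2.28-fold, adjusted p = 0.0433), with its other probe opposite.

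Among the other named rises in RCF, Lypla1, which removes palmitate from proteins, reached 1.12 ± 0.17 (adjusted p = 0.0412) and Sec24d, a coat protein of vesicles leaving the endoplasmic reticulum, 1.07 ± 0.16 (adjusted p = 0.0375). Amer2, a regulator of Wnt signalling, rose by 1.20 ± 0.20, and Rapgef4, a cyclic AMP sensor, by 1.14 ± 0.15, with 2 other probes opposite. The genes with the next smallest p among falls did not pass: Ccdc9 stood at −0.77 (adjusted p = 0.0597), Ammecr1 at −1.22 (adjusted p = 0.0719) and the p53 regulator Mdm4 at −1.10 (adjusted p = 0.0832). All 3 RCF arrays lay on one side of the control mean for each of the 9 named genes that passed. In all 47 genes passed limma, 40 higher and 7 lower, of which 24 had a symbol, 23 higher and 1 lower.

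Of the 8 lists past camera in RCF, none held a member past limma's threshold over all genes. B cell and plasma cell markers stood at −0.45, with 3 of 14 lower when adjusted over the list alone and 5 at an unadjusted p under 0.05 (adjusted p = 9e-06, adjusted p = 0.494 with an estimated correlation), and at −0.40, −0.44 and −0.62 in RCF 1 to 3. Cd79b was at −0.71 ± 0.19 (adjusted p = 0.147). For the other lists 0 members passed over the list alone by limma. MHC class II genes stood at −0.31, with 1 of 14 higher and 6 lower at an unadjusted p under 0.05 (adjusted p = 0.00237, adjusted p = 0.82 with an estimated correlation), and Cd74, the invariant chain, at −0.50. Interferon-stimulated genes stood at 0.31 with 5 of 23 higher at an unadjusted p under 0.05 (adjusted p = 0.00891, adjusted p = 0.825 with an estimated correlation), and Ifi44 at 0.80 ± 0.22. Alveolar macrophage markers stood at 0.23 with 6 of 15 higher at an unadjusted p under 0.05 (adjusted p = 0.0144, adjusted p = 0.82 with an estimated correlation), and Siglecf, a receptor of alveolar macrophages and eosinophils, at 0.52 ± 0.15. Both of these calls were lost without RCF 2, at 0.28 and 0.17 (adjusted p = 0.0519 each), and with replicate number as a block, at 0.22 and 0.21 (adjusted p = 0.0829 and 0.141), and alveolar macrophage markers stood at 0.37 without control 2.

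Heart and skeletal muscle genes stood at −0.84 in RCF, with 0 of 16 at an unadjusted p under 0.05 by limma (adjusted p = 0.00237, adjusted p = 0.825 with an estimated correlation). Controls ranged from −1.10 to 0.94 on this list, and the call was lost without control 2 (−0.49, adjusted p = 0.0859) and without RCF 3 (−0.41, adjusted p = 0.113). Immediate early genes stood at −0.34 with 4 of 16 lower at an unadjusted p under 0.05 (adjusted p = 0.0131, adjusted p = 0.825 with an estimated correlation). That list was lost without control 5, RCF 1 and RCF 2, at −0.22, −0.28 and −0.27 (adjusted p = 0.146, 0.219 and 0.0519). Cholesterol genes stood at −0.08 with 6 of 18 lower at an unadjusted p under 0.05 (adjusted p = 0.0256, adjusted p = 0.82 with an estimated correlation). Without control 2, control 4 and RCF 1 the list stood at −0.0051, −0.097 and −0.045 (adjusted p = 0.0868, 0.0549 and 0.219), and without control 5 and RCF 2 at −0.15 and −0.040. T cell and NK cell markers stood at −0.24, with 0 of 18 at an unadjusted p under 0.05 by limma (adjusted p = 0.045, adjusted p = 0.82 with an estimated correlation). Without control 2, 3 and 4 and RCF 1 and 2 it stood at −0.22, −0.20, −0.21, −0.14 and −0.20 (adjusted p = 0.148, 0.0555, 0.0710, 0.313 and 0.254).

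All 47 RCF genes remained with slide as a fixed block, among 457, and with slide as a random block among 467, and all 47 had the same sign within slides 1 and 3. Fndc3a stood at 1.33 and 1.35 within slides 1 and 3, and Fpgt at 1.08 and 1.05. The B cell list was at −0.39 with slide as a fixed block, −0.43 within slide 1 and −0.38 within slide 3, and MHC class II at −0.27, −0.16 and −0.29. Interferon-stimulated genes were at 0.38, 0.22 and 0.26, alveolar macrophage markers at 0.21, 0.17 and 0.41, heart and muscle genes at −0.78, −0.31 and −0.83, and immediate early genes at −0.32, −0.41 and −0.34. The cholesterol (−0.08) and T and NK (−0.21) lists no longer passed with slide as a fixed block (adjusted p = 0.0659 each), and stood at −0.20 and −0.34 within slide 1 and −0.05 and −0.10 within slide 3. Without control 1 to 5 in turn 9, 55, 24, 8 and 7 genes passed, and without RCF 1 to 3 12, 0 and 37. Without RCF 2, where 0 passed limma, 3094 had an unadjusted p under 0.05. Of the 9 named genes past the threshold, 7, 2, 4, 6 and 6 were lost without control 1 to 5 and 6, 9 and 6 without RCF 1 to 3.

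The mean of the 3 fibres was set against vehicle, a comparison that a single fibre can carry. The B cell genes Cd79b, Tnfrsf17 and Pou2af1 fell, and Cyp2b10 and Eppin rose. Cd79b fell by 0.88 ± 0.14 (1.84-fold, adjusted p = 0.0169, 9 fibre against 5 control arrays), Tnfrsf17, a survival receptor of plasma cells, by 1.18 ± 0.28 (adjusted p = 0.0481) and the B cell coactivator gene Pou2af1 by 0.39 ± 0.09 (adjusted p = 0.0481). Cyp2b10, a drug-metabolizing cytochrome P450, rose by 0.55 ± 0.10 (1.46-fold, adjusted p = 0.024). Eppin rose by 1.80 ± 0.21 (3.47-fold, adjusted p = 0.0054) and Zfp560 by 1.53 ± 0.21 (2.89-fold, adjusted p = 0.00948).

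Other named rises were Clca3a2, a chloride channel regulator, at 1.64 ± 0.32, the ubiquitin ligase gene Trim40 at 1.59 ± 0.36 and P2ry12, the ADP receptor of microglia and platelets, at 1.40 ± 0.22. Slc16a4, Hs3st3a1 and Iqub reached 1.31, 1.26 and 1.26, and the clock genes Per2 and Nr1d2 1.02 (adjusted p = 0.0277) and 0.58 (adjusted p = 0.0282). Lox rose by 0.88 (adjusted p = 0.0329), Chil4, a chitinase-like gene of alternatively activated macrophages, by 0.66 (adjusted p = 0.0381) and Trp53inp1, a p53 target, by 0.67 (adjusted p = 0.03). Among falls, Cnfn, a component of the cornified envelope, stood at −2.26 ± 0.42 and Ly6d, a surface protein of keratinocytes and lymphoid progenitors, at −1.23 ± 0.22. Both were highest in control 2, at 4.79 and 4.26, and Ly6d was at 2.80 to 3.1 in the other controls. Usp37, a deubiquitinase, fell by 1.47 ± 0.25, Ammecr1 by 1.16 ± 0.18, Hmbox1 by 1.33, the olfactory receptor gene Olfr1163 by 2.20 and Cbx5, a heterochromatin protein with its other probe opposite, by 1.13. For each gene named here as past the threshold all 9 fibre arrays lay on one side of the control mean, except Nr1d2 with 8 of 9. In all 790 genes passed limma, 613 higher and 177 lower, and 491 had a symbol.

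The B cell and plasma cell list stood at −0.51 for the mean of the fibres, with 3 of 14 lower over all genes and 9 when adjusted over the list alone (adjusted p = 1.24e-06, adjusted p = 0.348 with an estimated correlation). All 9 fibre arrays lay below the control mean, at −0.77, −0.50 and −0.64 in VCF, −0.27, −0.58 and −0.45 in CCF and −0.40, −0.44 and −0.62 in RCF. T and NK cell markers stood at −0.31, with 1 lower of 18 over all genes and 2 over the list alone (adjusted p = 0.00753, adjusted p = 0.609 with an estimated correlation). Cd2 fell by 0.41 ± 0.09 (adjusted p = 0.0369). Without the 3 dim arrays this list stood at −0.19 (adjusted p = 0.0804). The xenobiotic list stood at 0.30, with 2 of 14 higher over all genes and over the list alone (adjusted p = 0.0172, adjusted p = 0.388 with an estimated correlation), and lost the call with replicate number as a block (0.18, adjusted p = 0.124). Cell cycle genes stood at −0.18 with 0 of 25 over all genes and over the list alone, and 6 lower at an unadjusted p under 0.05 by limma (adjusted p = 0.0172, adjusted p = 0.835 with an estimated correlation). The arrays of VCF lay at −0.75, −0.77 and −0.36 on that list and those of CCF on the other side of the control mean, at 0.087, 0.19 and 0.38. MHC class II genes stood at −0.25, and at 0.014 in CCF alone, with 0 of 14 lower over all genes by limma, 6 at an unadjusted p under 0.05 and 2 over the list alone (adjusted p = 0.0203, adjusted p = 0.756 with an estimated correlation). Under quantile scaling this list stood at −0.078 (camera adjusted p = 0.152), and with normexp background as well at −0.092 (camera adjusted p = 0.0855). Eosinophil, basophil and mast cell markers stood at −0.35, with 0 of 12 over all genes by limma, 3 lower at an unadjusted p under 0.05 and 2 over the list alone (adjusted p = 0.0242, adjusted p = 0.388 with an estimated correlation). These last calls were lost without some arrays, at medians that moved by less than 1.5 times. Without control 3 and VCF 1 they were −0.14 and −0.18 for cell cycle (adjusted p = 0.102 and 0.0599), −0.20 and −0.23 for MHC class II (adjusted p = 0.0895 and 0.0599) and −0.33 and −0.32 for the eosinophil list (adjusted p = 0.0673 and 0.0599). Without control 2 they were −0.14 for cell cycle (adjusted p = 0.0701) and −0.24 for the eosinophil list (adjusted p = 0.172).

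The other 4 lists that camera called for the mean of the fibres did so at an adjusted p of 0.041 each. Ciliated cell genes stood at 0.16, with 2 of 20 higher over all genes and 3 over the list alone (adjusted p = 0.835 with an estimated correlation), and Sntn, a protein of the ciliary tip, rose by 0.64 ± 0.15. Heat shock genes stood at 0.26, with 0 of 12 over all genes and over the list alone by limma and 3 higher at an unadjusted p under 0.05 (adjusted p = 0.835 with an estimated correlation). Cholesterol genes stood at −0.12, with 0 of 18 over all genes and over the list alone by limma and 5 lower at an unadjusted p under 0.05 (adjusted p = 0.733 with an estimated correlation). Heart and muscle genes stood at −0.51, with 0 of 16 over all genes and at an unadjusted p under 0.05 by limma (adjusted p = 0.835 with an estimated correlation). Ciliated genes did not pass without control 1, 2, 3 and 4, VCF 1 and 2, CCF 1 and RCF 2, at 0.13, 0.15, 0.18, 0.14, 0.14, 0.17, 0.13 and 0.15 (adjusted p = 0.0874, 0.0676, 0.102, 0.0687, 0.0750, 0.0534, 0.164 and 0.0910). Heat shock genes did not without control 1, 2 and 4, VCF 1 and 3, CCF 3 and RCF 2, at 0.20, 0.34, 0.18, 0.25, 0.24, 0.29 and 0.26 (adjusted p = 0.231, 0.0661, 0.206, 0.0604, 0.0948, 0.0828 and 0.0871). Cholesterol genes did not without control 2, 3 and 4, VCF 1, CCF 1 and RCF 1, at −0.10, −0.13, −0.10, −0.14, −0.12 and −0.13 (adjusted p = 0.127, 0.0673, 0.0687, 0.0833, 0.0743 and 0.0769), nor with slide as a fixed block (adjusted p = 0.0742). Heart and muscle genes did not without control 2, 3 and 5, VCF 1 and 3, CCF 2 and 3 and RCF 3, at −0.25, −0.35, −0.33, −0.49, −0.47, −0.40, −0.41 and −0.33 (adjusted p = 0.436, 0.239, 0.141, 0.0833, 0.0596, 0.104, 0.109 and 0.129), and stood at −0.77 without control 1 and without control 4.

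Of these 790 genes, 783 remained with slide as a fixed block among 1694, and with slide as a random block 790 among 2238. Within slides 1, 2 and 3, 790, 790 and 787 had the same sign, and Olfr1163 stood at −2.63, −4.28 and 0.05. Within slides 1, 2 and 3 the B cell list was at −0.56, −0.67 and −0.38, the T and NK list at −0.43, −0.18 and −0.10, the xenobiotic list at 0.26, 0.19 and 0.32 and the cell cycle list at −0.32, −0.15 and 0.02. The values with a fixed block were −0.56, −0.30, 0.25 and −0.24. MHC class II genes were at −0.23, −0.03 and −0.29, eosinophil markers at −0.52, −0.64 and −0.21, ciliated cell genes at −0.02 within slide 3, and heart and muscle genes at −0.04, −1.29 and −0.83. Leaving out control 1 to 5 gave 128, 1030, 746, 61 and 185 genes, VCF 1 to 3 1033, 257 and 290, CCF 1 to 3 525, 261 and 486 and RCF 1 to 3 326, 244 and 210. Of 31 named genes past the threshold, 25, 6, 11, 29 and 22 were lost without control 1 to 5, 3, 19 and 14 without VCF 1 to 3, 10, 19 and 11 without CCF 1 to 3 and 17, 18 and 20 without RCF 1 to 3. Eppin and Zfp560 passed without each array in turn.

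The fibre after carbonization was tested directly against the fibre before recycling. The stefin genes Stfa2 and Cstdc4 fell by 4.07 ± 0.48 (16.8-fold, adjusted p = 0.00697) and 3.85 ± 0.42 (14.5-fold, adjusted p = 0.00587), Cxcr2 by 3.89 ± 0.59 (14.8-fold, adjusted p = 0.023) and Retnlg by 2.87 ± 0.34 (7.33-fold, adjusted p = 0.00697). Mki67 rose by 1.41 ± 0.17 (2.67-fold, adjusted p = 0.00697), Ckap2 by 1.80 ± 0.26 (3.47-fold, adjusted p = 0.0175) and Crabp1 by 1.71 ± 0.26 (3.28-fold, adjusted p = 0.023). Stfa2l1 fell by 3.8 ± 0.51, S100a8 by 2.86 ± 0.40 and S100a9 by 2.49 ± 0.33. The DNA repair gene Hrob rose at least 2.42-fold and Shcbp1 at least 1.99-fold from levels not above background in VCF. Birc5, or survivin, rose by 1.08 ± 0.19 (adjusted p = 0.0498) and Cd8a, the coreceptor of cytotoxic T cells, by 1.07 ± 0.17 (adjusted p = 0.0337). Each of these genes had all 3 CCF arrays on one side of the VCF mean.

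The neutrophil list stood at −2.27 in CCF against VCF, with 7 of 15 lower over all genes and 8 when adjusted over the list alone (adjusted p = 1.7e-11, adjusted p = 0.0760 with an estimated correlation). Cell cycle genes stood at 0.94, with 2 of 25 higher over all genes and 19 over the list alone (adjusted p = 5.66e-18, adjusted p = 0.0760 with an estimated correlation). T and NK cell markers stood at 0.42, with 1 of 18 and 3 (adjusted p = 1.32e-05, adjusted p = 0.174 with an estimated correlation). Thymus genes, 4 measured, stood at 0.73 without passing (camera adjusted p = 0.0916), at −0.47, 0.80 and 0.37 in CCF 1 to 3 and −0.41, −0.55 and −0.43 in VCF 1 to 3. The other lists past camera had 0 members past limma over all genes. Erythroid genes stood at 2.08, with 7 of 9 higher over the list alone and 8 at an unadjusted p under 0.05 (adjusted p = 8.86e-09, adjusted p = 0.176 with an estimated correlation), and Hbb-b2 at 2.08. Extracellular matrix genes stood at 0.50, with 7 of 28 higher over the list alone and 10 higher and 1 lower at an unadjusted p under 0.05 (adjusted p = 4.59e-05, adjusted p = 0.0760 with an estimated correlation). The gelatinase gene Mmp2 was at 1.20 and the collagen gene Col3a1 at 1.01, and the list at 0.30 without CCF 3. The T and NK list stood at 0.66 without CCF 2. Interferon-stimulated genes stood at 0.37, with 6 of 23 higher over the list alone and 7 at an unadjusted p under 0.05 (adjusted p = 1.7e-05, adjusted p = 0.321 with an estimated correlation), and at 0.62 without VCF 3.

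Another 4 lists past camera in CCF against VCF lost the call without some single arrays. Alveolar macrophage markers stood at 0.26 with 1 of 15 higher over the list alone and 4 at an unadjusted p under 0.05 (adjusted p = 0.00277, adjusted p = 0.321 with an estimated correlation), and at 0.15 without CCF 3 (adjusted p = 0.111). MHC class II genes stood at 0.44 with 3 of 14 higher and 1 lower over the list alone and 4 and 1 at an unadjusted p under 0.05 (adjusted p = 0.00277, adjusted p = 0.321 with an estimated correlation), and at 0.23 without CCF 3 (adjusted p = 0.115). The costimulator gene Cd80 of that list was at −1.12. Immediate early genes stood at −0.29 with 0 over the list alone by limma and 3 of 16 lower at an unadjusted p under 0.05 (adjusted p = 0.0197, adjusted p = 0.71 with an estimated correlation). Without VCF 2, VCF 3, CCF 2 and CCF 3 the list stood at −0.15, −0.087, −0.22 and −0.23 (adjusted p = 0.198, 0.396, 0.0788 and 0.0637), and without VCF 1 at −0.58. The inflammasome list stood at −0.14 with 2 lower over the list alone and 3 at an unadjusted p under 0.05 (adjusted p = 0.0359, adjusted p = 0.321 with an estimated correlation). Without VCF 2, VCF 3, CCF 1 and CCF 2 it stood at −0.11, −0.23, −0.17 and −0.13, some of them larger than in full (adjusted p = 0.198, 0.0858, 0.0666 and 0.157). The adjusted p was 0.0714 with slide as a fixed block and 0.0570 with replicate number as a block. Without CCF 3 the list stood at −0.25.

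In CCF against VCF 68 genes passed limma, 29 higher and 39 lower, and 46 had a symbol. All 68 remained among 563 with slide as a fixed block and among 656 with slide as a random block, and all had the same sign within slides 1 and 2. Within slides 1 and 2 the neutrophil median was −2.0 and −2.17, that of cell cycle 0.94 and 0.88, erythroid 1.97 and 1.80, T and NK 0.43 and 0.43, extracellular matrix 0.42 and 0.46, interferon 0.48 and 0.16, alveolar macrophage 0.01 and 0.53, MHC class II 0.34 and 0.56 and immediate early −0.08 and −0.82. Slides were balanced here, so that the fixed block left the medians as they were. Without VCF 1 to 3 the count was 29, 25 and 30, and without CCF 1 to 3 it was 30, 21 and 22. Of 14 named genes past the threshold 6, 8, 6, 5, 9 and 8 were lost in these fits, and Shcbp1, Stfa2, Cstdc4, Mki67 and Retnlg passed in each.

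In RCF against VCF, 3 genes passed limma's threshold, but not with replicate number as a block (adjusted p = 0.21 each). Each was higher in all 3 RCF arrays than the VCF mean. Ces2e rose by 1.36 ± 0.15 (2.57-fold, adjusted p = 0.0284), Kif20a by 1.33 ± 0.15 (2.51-fold, adjusted p = 0.0295) and Adgre4, an adhesion receptor of macrophages, by 1.40 ± 0.17 (2.63-fold, adjusted p = 0.0402). Cell cycle genes stood at 0.53, with 0 of 25 over all genes, 8 higher when adjusted over the list alone and 10 at an unadjusted p under 0.05 by limma (adjusted p = 7.16e-09, adjusted p = 0.272 with an estimated correlation), with Mki67 at 1.03 (adjusted p = 0.0966). Neutrophil markers stood at −1.18, with 0 of 15 over all genes, 3 lower over the list alone and 7 at an unadjusted p under 0.05 by limma (adjusted p = 8.38e-08, adjusted p = 0.262 with an estimated correlation), and Stfa1 at −2.64 (adjusted p = 0.0868). Without RCF 3 the neutrophil list still passed at −0.39. Erythroid genes stood at 0.84, with 4 of 9 higher over the list alone and 8 at an unadjusted p under 0.05 (adjusted p = 1.39e-06, adjusted p = 0.272 with an estimated correlation).

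A further 7 lists passed camera in RCF against VCF, with 0 members past limma over all genes. T and NK cell markers stood at 0.37, with 1 of 18 higher over the list alone and 5 at an unadjusted p under 0.05 (adjusted p = 0.000232, adjusted p = 0.272 with an estimated correlation), beside thymus genes at 0.42 (camera adjusted p = 0.429). Interferon-stimulated genes stood at 0.45, with 2 of 23 and 6 (adjusted p = 6.26e-05, adjusted p = 0.5 with an estimated correlation), and at 0.27 without VCF 1 (adjusted p = 0.0855). Alveolar macrophage markers stood at 0.26, with 2 of 15 and 3 (adjusted p = 0.000436, adjusted p = 0.272 with an estimated correlation). Extracellular matrix genes stood at 0.39, with 3 of 28 and 10, and 1 lower (adjusted p = 0.000436, adjusted p = 0.262 with an estimated correlation). Without RCF 3 the T and NK list stood at 0.23, and without VCF 2 the matrix list at 0.26. The lower lists had 0 members past the threshold over the list alone by limma. Ciliated cell genes stood at −0.18 with 5 of 20 lower at an unadjusted p under 0.05 (adjusted p = 0.000131, adjusted p = 0.5 with an estimated correlation), and at −0.10 without VCF 2 and −0.31 without VCF 3. Immediate early genes stood at −0.45 with 2 of 16 (adjusted p = 9.49e-05, adjusted p = 0.5 with an estimated correlation) and lost the call without VCF 3 (−0.37, adjusted p = 0.0515), standing at −0.77 without VCF 1. Heat shock genes stood at −0.37 with 2 of 12 (adjusted p = 0.000496, adjusted p = 0.541 with an estimated correlation), and lost it without VCF 3 as well (−0.19, adjusted p = 0.0711).

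Both groups stood together on slide 1 alone, where the 3 genes kept their sign, and the medians of cell cycle, neutrophil, erythroid, T and NK, interferon, alveolar macrophage and matrix genes were 0.76, −0.48, 1.14, 0.23, 0.65, 0.27 and 0.37. The medians with a fixed block for slide were 0.77, −0.78, 0.92, 0.37, 0.49, 0.45 and 0.38. For ciliated, immediate early and heat shock genes the slide 1 values were −0.33, −0.35 and −0.17 and those with a fixed block −0.28, −0.44 and −0.33. With slide as a fixed block 2 of the 3 genes remained among 7, without Adgre4 (adjusted p = 0.0851), and 2 as a random block. With replicate number as a block 0 genes passed limma (3027 at an unadjusted p under 0.05) and 10 lists camera. Without VCF 1, VCF 2 or VCF 3 0 genes passed limma (2762, 2500 and 2503 at an unadjusted p under 0.05), without RCF 1 1, without RCF 2 0 (1969) and without RCF 3 26.

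The fired against the carbonized fibre gave 1 gene past limma, higher in RCF and without a symbol, which did not pass with slide as a fixed or random block. Neutrophil markers stood at 1.40, with 8 of 15 higher when adjusted over the list alone and 0 over all genes by limma, 8 at an unadjusted p under 0.05 (camera adjusted p = 0.000133, adjusted p = 0.738 with an estimated correlation). S100a9 was at 1.72, S100a8 at 1.95, Retnlg at 1.62 and Cxcr2 at 2.51, each with an adjusted p of 0.402. Cell cycle genes stood at −0.32, with 0 of 25 over all genes and over the list alone by limma and 5 lower at an unadjusted p under 0.05 (adjusted p = 2.77e-06, adjusted p = 0.738 with an estimated correlation), and the mitotic kinase gene Plk1 at −0.75. On slide 1, the slide that held both groups, these lists stood at 1.76 and −0.06, and with slide as a fixed block at 1.44 and −0.09. The genes closest to the threshold, C2cd4d at 1.23, the myeloid receptor gene Trem3 at 1.34, Tspan9 at −1.34 and the helicase gene Ddx43 at −0.75, had an adjusted p of 0.402 each.

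The remaining lists past camera in RCF against CCF had 0 members past limma over all genes and over the list alone. MHC class II genes stood at −0.21, with 3 lower at an unadjusted p under 0.05 (adjusted p = 0.00716, adjusted p = 0.738 with an estimated correlation), and lost the call without CCF 3 (−0.02, adjusted p = 0.279) and with slide as a fixed block (−0.18, adjusted p = 0.0609), at −0.05 within slide 1 and −0.37 without CCF 2. Cytokine and chemokine genes stood at −0.31, with 2 lower (adjusted p = 0.0345, adjusted p = 0.738 with an estimated correlation). Without CCF 1, CCF 3, RCF 1 and RCF 3 the list stood at −0.21, −0.30, −0.33 and −0.18 (adjusted p = 0.0579, 0.205, 0.119 and 0.161), and with a fixed block at −0.11 (adjusted p = 0.195). Heat shock genes stood at −0.20, with 0 at an unadjusted p under 0.05 (adjusted p = 0.0345, adjusted p = 0.738 with an estimated correlation). Without CCF 2, CCF 3, RCF 1 and RCF 3 it stood at −0.23, −0.23, −0.26 and −0.18 (adjusted p = 0.0701, 0.168, 0.190 and 0.0637), and the adjusted p was 0.0538 with a fixed block. Ciliated cell genes stood at −0.14, with 1 lower at an unadjusted p under 0.05 (adjusted p = 0.0409, adjusted p = 0.738 with an estimated correlation), −0.18 with a fixed block and −0.21 within slide 1. Without CCF 1, RCF 1 and RCF 3 it stood at −0.011, −0.14 and −0.071 (adjusted p = 0.681, 0.179 and 0.0988), and without CCF 3 at −0.23. As for genes, without CCF 1, CCF 2 or CCF 3 0 passed limma (2069, 2872 and 2122 at an unadjusted p under 0.05), without RCF 1 2, without RCF 2 0 (1709) and without RCF 3 25.

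**Figure D2:**
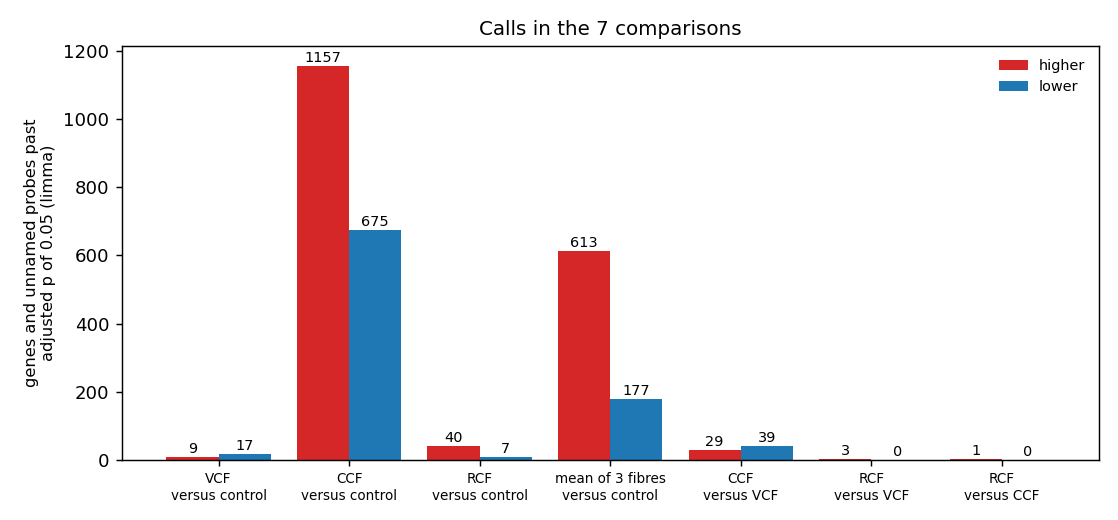
Number of genes past limma's adjusted p threshold of 0.05 in each of the 7 comparisons, with bars for higher and lower genes. CCF against control gave 1157 higher and 675 lower genes and VCF against control 9 and 17.

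Of the genes classically raised by inhaled particles, most did not pass the test. Ccl2, a monocyte chemokine, stood at −0.14 in VCF (adjusted p = 0.964) and 0.37 in CCF (adjusted p = 0.624), the acute phase gene Saa3 at −0.04 (adjusted p = 0.994) and 0.94 (adjusted p = 0.291), and the macrophage elastase gene Mmp12 at 0.20 (adjusted p = 0.95) and 0.86 (adjusted p = 0.254). Timp1, a metalloproteinase inhibitor, stood at −0.41 in VCF (adjusted p = 0.654) and the p53 target Cdkn1a at 0.93 (adjusted p = 0.236). Spp1 stood at 0.42 in CCF (adjusted p = 0.33), 0.21 in RCF (adjusted p = 0.796) and 0.73 ± 0.19 for the mean of the fibres (adjusted p = 0.0584). In no comparison with control did camera call the lists for cytokines, inflammasome, acute phase, lipid-laden or alternatively activated macrophages, oxidative stress, p53, clock, club, mucous, endothelial, fibroblast, adipose, thymus or tracheal genes. For the mean of the fibres their medians were −0.01, 0.05, 0.18, −0.05, 0.01, −0.09, 0.03, 0.11, 0.00, 0.27, −0.07, −0.07, −0.12, −0.13 and −0.11.

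Genes of tissues outside the lung parenchyma were high in single arrays of several groups. Of 12 measured squamous epithelium markers, chosen after the values were seen, 9 were highest in control 2, with a median 5.72 above each gene's median over the arrays, where the adipose list also stood 3.40 above the control mean. That list stood 2.11 above it in VCF 2, the array with the highest neutrophil median (1.40), and 1.0 in CCF 1, against −1.59 in control 4 and −2.02 in CCF 2. In control 2 Lor, for loricrin, was at 7.53 and the keratinocyte gene Krtdap at 6.02. Of 13 measured liver markers, also chosen after the values were seen, 11 had RCF 1 and RCF 2 as the highest arrays, with medians of 4.27 and 4.29, against 0.13 in RCF 3. Alb, serum albumin, was at 1.83 and 1.70 in RCF 1 and RCF 2, and the urinary protein gene Mup1 at 3.71 and 3.59.

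**Figure D3:**
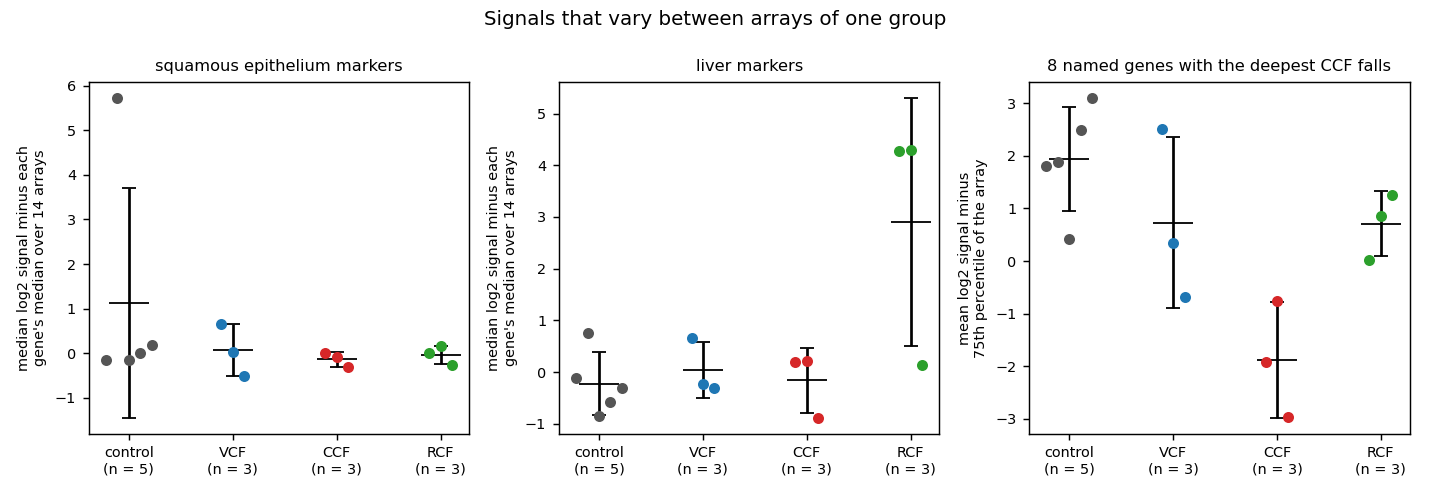
Per-array log2 signal for the 14 arrays by group, in 3 panels: the median of 12 squamous epithelium markers and of 13 liver markers, each minus the gene's median over the arrays, and the mean of the 8 deepest named CCF falls. Points are arrays; control 2 reaches 5.72 in the first panel and RCF 1 and RCF 2 4.27 and 4.29 in the next.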

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

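Of the tests in this part, all were chosen after the results were seen, except the search for a single control array apart from the other 4, whose scope was widened to 273 genes after a first look.

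A control array lay far from the other controls, by Dixon's ratio with a critical value of 0.71, for 31 of 273 genes and 5 of 33 lists, where chance gives about 1 in 20. In control 2 the normalized log2 signal was 5.67 for Scd1, 2.80 for Cd1d1, 3.16 for Acta1, 3.74 for Myh1, 5.48 for Cidea, 3.96 for Ucp1, 6.51 for C3 and 4.26 for Ly6d, each above the other controls. It was also −3.88 for Shcbp1, 0.34 for Birc5, −0.053 for Chad, −0.26 for Clca1 and −1.96 for Cxcl13, above the others, and 2.55 for Gadd45b, 5.80 for Hopx and −2.76 for Hmbox1, below them. In control 2 3 list medians stood apart, at 0.58 for acute phase, 0.37 for alternatively activated macrophage and 0.31 for eosinophil, basophil and mast cell genes. In control 1 Hydin stood apart at −0.79. In control 3 this held for Col2a1 at −3.69, Slc39a10 at −2.56, Dmrtb1 at −2.69, Nr1d2 at 2.37 and Tek at 1.62. In control 4 it held for Akr1b8 at 2.79, Rapgef4 at −2.66, Stfa2l1 at −1.54 and the inflammasome list at −0.12. In control 5 it held for Doc2b at −4.12, Hsp90aa1 at 5.91, Lox at 0.44, Ear1 at 2.60, Foxj1 at 2.78, Trem3 at −1.55 and the T and NK cell list at −0.13.

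In control 2 and in RCF 1 and RCF 2 genes of other tissues were high, and whether RNA of neighbouring tissue or liver in those samples is the source stays open. Of 12 measured squamous epithelium markers 9 were highest in control 2, with Krt13 at 5.06 and Sfn at 5.29 against at most 3.30 elsewhere. The fixed adipose list stood 3.40 above the control mean there, but also 2.11 in VCF 2. Of 13 measured liver markers 11 had RCF 1 and RCF 2 as the highest arrays, with Serpina1a at 1.86 and 2.08. Markers seen before they were chosen decide nothing, and of those not seen 2 of 5 squamous markers were highest in control 2 and 3 of 5 liver markers in RCF 1 and RCF 2, too few to decide on neighbouring tissue or liver. For control 2 the design gives no biological explanation to test, and for RCF an effect of the fibre stays open, untested, against RCF 3 at 0.13.

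The deepest falls in CCF moved together, and a signal of the probe rather than of the gene is a candidate explanation. With group means removed, the median of the 28 correlations between the 8 genes over the arrays was 0.937, which argues against a response to CCF alone. Of the called genes that moved with them, 12 had another probe: their main probes had a median of −2.68 and the other probes 0.0790, with 5 of 12 on the same side. The other 91 called falls with a second probe stood at −1.16 and −0.26, with 59 on the same side. What the probes share was not tested, and an effect of CCF on top of it stays open.

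In VCF neutrophil markers were higher and lymphocyte and erythroid markers lower than in control. One change in the share of blood would move neutrophil and erythroid markers the same way, and the erythroid median of −1.36 beside a neutrophil median of 0.90 argues against it as the cause of both the rise and the falls. A lower share of blood stays open for the falls alone, the smallest of which was the T and NK median of −0.56, and so does less thymus tissue (thymus median −0.44 on 4 genes) for the T and NK markers. Without the dim array VCF 1 the neutrophil median was 1.11, and the smaller of the within-slide medians was 0.94, which argues against that array and against slides as the whole cause. An effect of VCF on leukocytes remains the hypothesis that may fit, and the camera calls were lost with an estimated correlation.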

How the results depend on the processing

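The fits without the 3 dim arrays, of scan day 1 only, with scan day as a block, with the second-highest probe and with normexp on the median signal were chosen after the data were seen. In this part the order of counts is VCF, CCF, RCF and the mean of the fibres against control, then CCF against VCF, RCF against VCF and RCF against CCF, and the cause of a change was not tested unless said. Limma's counts in full were 26, 1832, 47, 790, 68, 3 and 1 genes, and camera's 14, 3, 8, 10, 10, 10 and 6 lists.

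Directions of called genes, chosen on these arrays, held on them more than calls. On second probes 61.1% of CCF calls kept the side. Of 547 values of named genes, 494 kept their side of the threshold with quantile scaling and 48 lost the call, against 458 and 89 with normexp and the 75th percentile, 503 and 15 with slide as a fixed block and 437 and 110 with replicate number as a block. Most of the 547 had not passed in full. With replicate number as a block 0 of 15, 38, 9, 31, 14 and 3 named calls remained, in the order above up to RCF against VCF. Of 4852 values with 1 array left out 4280 kept their side, 544 lost the call, 28 gained it and 0 called values reversed. With the mean of a gene's probes 2 reversed, Hydin at −0.60 in CCF (adjusted p = 0.102) and −0.18 for the mean of the fibres (adjusted p = 0.604), where its probes go opposite ways. With array weights the heart and muscle list reversed for the mean of the fibres, at 0.045 (adjusted p = 0.937). Some values that had not passed changed sign and are counted by their side alone: 4, 9, 3 and 9 gene values in those 4 settings, and 66 gene and 193 list fits with 1 array left out. Of 4 ways to scale, 0 reversed a named gene past the threshold. No such gene had its log2 difference moved by over 1.5 times with 1 array left out or with slide as a block. In lists past camera the median, mean and test had 1 sign, and of the others 2, 4, 5, 5, 4, 7 and 7 differed in sign between them.

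Quantile scaling gave 2 genes for VCF, 6 for RCF, 487 for the mean, 0 for RCF against VCF and 0 for RCF against CCF, and 8 lists for CCF and 5 for RCF. Normexp with the 75th percentile gave 0, 412, 0, 40, 12, 0 and 0 genes and 7 lists for CCF. Normexp with quantile scaling gave 31 for RCF, 0 for RCF against VCF and 0 for RCF against CCF, and 6 lists for CCF and 5 for RCF. The authors' table gave 1235 for the mean and 0 for RCF against CCF, and 1 list for CCF and 4 for the mean. Without a background filter there were 0, 372, 0, 49, 23, 0 and 0 genes and 6 lists for CCF, and the median of all genes was 0.16 for VCF, 0.13 for CCF, −0.13 for CCF against VCF and −0.11 for RCF against VCF. With probes above background on all 14 arrays, so that fewer genes were tested, there were 96 for VCF, 195 for RCF, 1645 for the mean, 190 for CCF against VCF, 10 for RCF against VCF and 0 for RCF against CCF, with 1 list for CCF and 4 for the mean. The mean of a gene's probes gave 24 for RCF, 417 for the mean and 0 for RCF against CCF, and 7 lists for CCF. With genes of several probes alone, the highest probe gave 1028 CCF genes and the second 472, mostly without the same call on the highest.

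A fixed block for slide gave 457 genes for RCF, 1694 for the mean, 563 for CCF against VCF, 7 for RCF against VCF and 0 for RCF against CCF. As a random block slide gave 95, 2945, 467 and 2238 against control, 656 for CCF against VCF and 0 for RCF against CCF. Slide 1 alone, with fewer arrays, gave 0 in all 7 comparisons, with 6 lists for CCF and 3 for RCF, and slide 3 alone 0 for RCF and 4 lists. Scan day 1 alone gave 0, 0, 0, 0, 9, 0 and 0, and 4 lists for RCF. Scan day as a block gave 7 for VCF, 752 for CCF, 79 for RCF, 132 for CCF against VCF and 0 for RCF against CCF. With replicate number as a block there were 0, 2, 0, 0, 0 and 0 genes in the first 6 comparisons and 5 lists for CCF, and RCF against CCF kept a count of 1 but 0 shared. Fits of only the groups compared gave 0 for VCF, 271 for CCF, 0 for RCF and 0 in each comparison of fibres. Without the 3 dim arrays there were 1, 418, 1, 168, 0, 0 and 0 genes and 6, 5 and 4 lists for CCF, RCF and the mean.

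A trended robust prior gave 82 for VCF, 1302 for the mean, 148 for CCF against VCF, 8 for RCF against VCF and 0 for RCF against CCF. Array weights gave 722, 4791, 5633, 5086, 242, 2791 and 2253, with a weight of 11.9 on RCF 2. An adjusted p under 0.10 gave 124, 3832, 245, 2132, 303 and 16 genes in the first 6 comparisons, and a fold of at least 2 left 700 for CCF, 28 for RCF and 147 for the mean. Estimated correlation left 0 lists for VCF, 0 for CCF, 0 for RCF and 0 for the mean, with the smallest adjusted p at 0.0604, 0.765, 0.494 and 0.348, and 0 between fibres. Fry called 8, 0, 0 and 2 lists against control.

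With 1 array left out the counts ran from 0 to 28 for VCF, 258 to 2717 for CCF, 0 to 55 for RCF, 61 to 1033 for the mean, 21 to 30 for CCF against VCF, 0 to 26 for RCF against VCF and 0 to 25 for RCF against CCF. The lists ran from 12 to 16, 3 to 8, 4 to 8, 4 to 10, 8 to 13, 9 to 14 and 4 to 10. Of the 57 counts of 0 genes by limma over all settings, each came with 1215 to 5220 genes at an unadjusted p under 0.05. Chance alone would give such a p to a share of about 0.05 of the genes tested, so that these counts by themselves do not show remaining signal. VCF 1 and CCF 2 had the lowest shares of probes above background (49.4% and 50.9%), while RCF 1, also dim, had 60.8%.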

Other observations

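The comparisons with splits that part the numbered pairs and with splits that keep the slides and the look at other probes were made after the results were seen, and the other tests of this part were chosen before.

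In CCF several genes of lists that did not pass camera were past limma's threshold. The endothelial list held members that went opposite ways: Tek, the angiopoietin receptor, rose by 0.76 (adjusted p = 0.0413) and the transcription factor gene Erg fell by 1.5 (adjusted p = 0.0458), with a list median of 0.0065 (camera adjusted p = 0.818). In the p53 and DNA damage list 3 members rose and 1 fell over all genes, with a median of 0.06 (camera adjusted p = 0.461). There Polk, a polymerase that copies damaged DNA, rose by 0.76 (adjusted p = 0.00698), with its other probe opposite. Siglecf rose by 0.59 (adjusted p = 0.0368), Cd8a by 0.61 (adjusted p = 0.0405), the mitotic kinase gene Plk1 by 0.67 (adjusted p = 0.0466) and Lbp, which binds bacterial lipopolysaccharide, by 0.64 (adjusted p = 0.0439). All 3 CCF arrays lay on one side of the control mean for each, and with slide as a fixed block Siglecf, Cd8a, Plk1, Tek and Erg no longer passed. Polk passed without each array in turn, and the others each lost the call without control 4, control 5, CCF 2 and CCF 3 singly, among other arrays.

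In splits of all the arrays compared, RCF, CCF and the mean of the fibres against control gave 47, 1832 and 790 genes as labelled. The highest other split gave 6, 2 and 1, and 1 of 56, 1 of 56 and 1 of 100 splits gave as many. These splits move arrays between slides, within which arrays correlate, so that they do not exclude chance on their own. Splits that keep the number of arrays of each group on each slide are 18 for RCF and 12 for CCF, too few for a share under 0.05, with 1 and 1 as the highest other. For RCF and CCF chance thus cannot be excluded by splits that keep the slides. For the mean, 1 of 100 drawn splits of that kind gave as many, with 78 as the highest other, which argues against chance for that comparison. For VCF against control 2 of 56 splits gave as many as 26, and a split with control 3, VCF 2 and VCF 3 on one side gave 199 genes, several times the real count, for a reason that was not tested. The pairing rule holds there. Only 8 splits part all 3 numbered pairs as the real one does, too few for a share under 0.05, with 26 genes as labelled and 0 as the highest other, and only 12 keep the slides, with 0 as the highest other; the splits with up to 199 part fewer pairs. Between fibres there are 10 splits, too few for a share under 0.05, with 68, 3 and 1 genes as labelled and 0, 0 and 1 as the highest other (1, 1 and 2 splits as large, the real one included). For RCF against VCF, where the pairing rule holds too, 4 splits part all 3 pairs, with 0 as the highest other.

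Comparisons with the same 5 controls share their chance values. Across 30443 genes, which are not independent, the log2 differences of VCF and CCF correlated at r = 0.497, against 0.375 for simulated unchanged groups with the same controls, and with control 1 and 2 for VCF and control 3 to 5 for CCF at −0.00149, or a median of 0.184 over all 20 splits of the controls (−0.00217 to 0.366). For CCF and RCF the values were 0.481, 0.381, 0.184 and 0.180 (−0.0685 to 0.464), and for VCF and RCF 0.357, 0.375, −0.0572 and −0.00260 (−0.173 to 0.164). Both CCF and RCF raised 35 genes, where 1.51 would be shared if calls were independent, and lowered 7, where 0.155 would be. VCF and CCF shared 4 higher and 3 lower genes (0.341 and 0.375), and VCF and RCF 1 and 2 (0.0118 and 0.00389), again with shared controls and in part shared slides.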
